A study of Homo sapiens with 16 samples.

How the data were processed

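Total RNA was taken from 16 samples of MOLM-13, a human acute myeloid leukaemia cell line. Cells had been treated for 4 days with 0.005% DMSO, with an EZH2 inhibitor at 1 µM, with a PRMT5 inhibitor at 1 µM, or with both inhibitors, with 4 replicates per treatment. The compounds are not named in the labels. EZH2 inhibitor and PRMT5 inhibitor are written EZH2i and PRMT5i, and the treatment with both is called the combination. RNA was purified on columns and made into paired-end Illumina libraries, per the labels' protocols, which state neither the library kit, its strandedness or any selection of RNA, nor the origin of the replicates.

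The authors deposited 1 table of RSEM expected counts per gene, with 1 column per sample and no scaling to depth. Reads were aligned to GRCh38.p7 with STAR 2.5.3 and counted with RSEM, per the submitters' processing notes, which do not give the RSEM version, the settings or the annotation. The table holds 60669 genes under versioned Ensembl identifiers joined to symbols, and 12.0% of its values are not whole numbers, since RSEM divides a read that matches several genes between them. All 16 columns were used. The 50 entries for the pseudoautosomal copies on chromosome Y hold 0 counts in all and played no part.

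Expected counts were rounded to whole numbers. Genes were kept with the filterByExpr function of edgeR 4.0.16 given the 4 groups, which left 16555 genes, of which 16437 have an entry in GENCODE release 29 and 12861 are protein-coding. Library sizes were scaled by trimmed mean of M values (TMM). One quasi-likelihood model with 4 group means was fitted to all 16 libraries, so that all comparisons share 1 estimate of the spread. The comparisons were EZH2i against DMSO, PRMT5i against DMSO, the combination against each of the other 3 groups, and the interaction, which is the effect of EZH2i in PRMT5-inhibited cells minus its effect in cells without PRMT5i on the log2 scale. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Every adjusted p given for a gene comes from this edgeR quasi-likelihood test, and CPM values use the TMM-scaled library sizes. Log2 CPM used a prior count of 2. Standard errors (SE) of log2 fold changes come from the same model. R 4.3.3, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used.

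A total of 27 gene lists with 647 different genes was written before the data were examined, and all 647 symbols are in the table. The lists cover PRC2 subunits, the PRMT family with PRMT5 partners, developmental regulators that are classic polycomb targets, CDK inhibitors, p53 targets, DNA replication with E2F targets, mitosis, replication-dependent histones, self-renewal genes of MLL leukaemia, interferon-stimulated genes, MHC class I, MHC class II, the core spliceosome, nucleolar and MYC targets, cytosolic ribosomal proteins, mitochondrially encoded proteins, the integrated stress and unfolded protein response, immediate early genes, the BCL2 family and sterol synthesis. A further 7 lists hold markers of monocytes and macrophages, granulocytes, erythroid cells, megakaryocytes, T and NK cells, B cells, and epithelial cells and fibroblasts. Each list was compared with the other genes by camera of limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the 27 lists of a comparison. The same test was run with the correlation between a list's genes estimated from the data. The fry test was run as well. It asks whether the genes of a list move, on balance, one way, and does not compare them with other genes.

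The set of genes that the text draws on was fixed by a rule before the data were examined, as were the comparisons, the tests, the lists and the main alternatives. The rule takes EZH2, PRMT5 and members of the PRC2 and PRMT lists past the threshold. For each single inhibitor against DMSO and the combination against DMSO and against PRMT5i it takes the 6 higher and the 6 lower protein-coding genes with the largest fold change among those past the threshold. These genes needed a mean of at least 5 CPM in the higher group and no overlap between the 2 groups. From each list with a member past the threshold it takes up to 2 members with the smallest p, and the text names only some of the PRC2, PRMT and other list members so taken. For the interaction it takes the 8 genes with the smallest p, and for overlaps of comparisons the 8 genes with the largest smaller fold change. These were protein-coding genes with a mean of at least 5 CPM in any of the 4 groups. Some further list members are named after their values were seen, to illustrate a count. Genes that share exon bases with another gene, or reads with a near-identical copy, are named as uncertain, since the strand setting of the counting is not stated.

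Comparisons that share libraries also share chance values. Unchanged groups were therefore simulated 20 times, the number of shared genes was set beside the number that independent lists give, and the shared libraries were divided between the comparisons. The tests of EZH2i against DMSO, of PRMT5i against DMSO, of the combination against PRMT5i and of the interaction were tried on simulated data drawn from the means and library sizes of the real table, with 200 genes changed, as was the set lower with PRMT5i and higher with EZH2i added. The other comparisons were not simulated in this way. At a fold of 1.5, 2 and 4, the test of EZH2i against DMSO found 41.8%, 77.6% and 89.4% of the changed genes among 16555, and 3.47% of its calls were unchanged genes, with 2.02% to 5.52% over the 4 tests. The simulated libraries hold neither the trends with GC content nor the division of replicates described below. The share of such calls in the real data may therefore be higher. The interaction test found 13.4%, 52.2% and 80.3% at the same folds, so that most interactions of 1.5-fold would be missed.

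The alternatives written before the data were examined were RLE size factors, total counts without a composition factor, no filter on low counts, a stricter filter (10 counts and 1 CPM in every library of a group), DESeq2 1.42.0, limma-voom, fits with only the groups compared, the replicate number as a block, a minimum absolute log2 fold change of 1, an adjusted p of 0.01, and leaving out each library in turn. Removing each library's trend with GC content (lowess, span 0.3), restricting the test to protein-coding genes, leaving out DMSO replicates 1 and 2 together, and a block of replicates 1 and 2 against replicates 3 and 4 were chosen after seeing the data. That block was set beside 99 drawn splits of each group into 2 and 2 libraries. Their effect on counts of genes and on calls of gene lists is given in the closing section. No library was left out of the reported values.

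Library totals lay between 31.1 and 52.9 M expected counts. A gene with no count in a library can be placed only below 3 counts of that library's total, a limit that covers counting error alone. Pairs of replicates correlated at 0.964 to 0.993 (log2 CPM), and the smallest chi-square per degree of freedom within a group was 8.92 over genes with at least 20 counts, so that replicates differed by more than counting error and depth alone does not set the precision.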

Results

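Gene expression was measured in MOLM-13, a human acute myeloid leukaemia cell line with an MLL fusion, after 4 days with 0.005% DMSO, with 1 µM EZH2i, with 1 µM PRMT5i, or with both. EZH2 is the methyltransferase of polycomb repressive complex 2 (PRC2), which places the repressive H3K27 methylation mark, and PRMT5 methylates arginines in histones, splicing factors and other proteins. Each of the 4 groups had 4 libraries. The DMSO libraries held 41.9, 31.1, 46.4 and 52.9 M expected counts in the order of their replicate numbers. The EZH2i libraries held 35.9, 48.8, 37.6 and 33.9 M, the PRMT5i libraries 51.3, 51.4, 43.6 and 40.6 M, and the combination libraries 49.8, 40.5, 35.6 and 35.3 M. Whether replicates are separate cultures is not given in the sources used here, so the p-values measure the spread between these samples.

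The first principal component of the 16555 tested genes held 36.5% of the variance and separated the libraries by PRMT5i. DMSO and EZH2i libraries scored −43.1 to −32.0 on it and PRMT5i and combination libraries 30.2 to 47.1. The second component held 16.8%, and its gene loadings correlated with GC content at −0.467. EZH2i libraries were spread on it from −49.5 to 2.06. DMSO libraries were spread from −32.1 in replicate 2 to 62.3 in replicate 1. DMSO replicate 1 also had the lowest TMM factor, 0.861, and 1.70% of its counts on genes of the mitochondrial genome, against 0.518%, 0.262% and 0.213% in the other DMSO libraries. This share includes the mitochondrial ribosomal RNAs. The mitochondrially encoded protein genes, on which the list counts below rest, had their lowest mean log2 CPM in DMSO replicate 1, 4.61 against 4.99 to 5.88 in the others.

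Replicates 1 and 2 differ from replicates 3 and 4 across the groups, a division looked for after seeing the data. With the 4 groups in the model, 263 genes passed for this term, 108 higher and 155 lower in replicates 3 and 4, and 39 of them by at least 1 on the log2 scale. The other 2 ways to pair the replicate numbers gave 0 genes each in edgeR. MPEG1, a macrophage perforin gene, had means of 2.93 CPM in replicates 1 and 2 and 7.24 CPM in replicates 3 and 4 with DMSO, 2.65 and 5.10 with EZH2i, 49.7 and 80.0 with PRMT5i, and 31.1 and 54.3 in the combination. EPS8, an actin regulator gene chosen after its values were seen, had 9.38 and 6.26, 14.3 and 9.24, 8.11 and 4.61, and 14.3 and 8.59 CPM in the same order. Whether the pairs are batches is not stated in the sources used here, and the values below come from the model without this term.

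**Figure D1:**
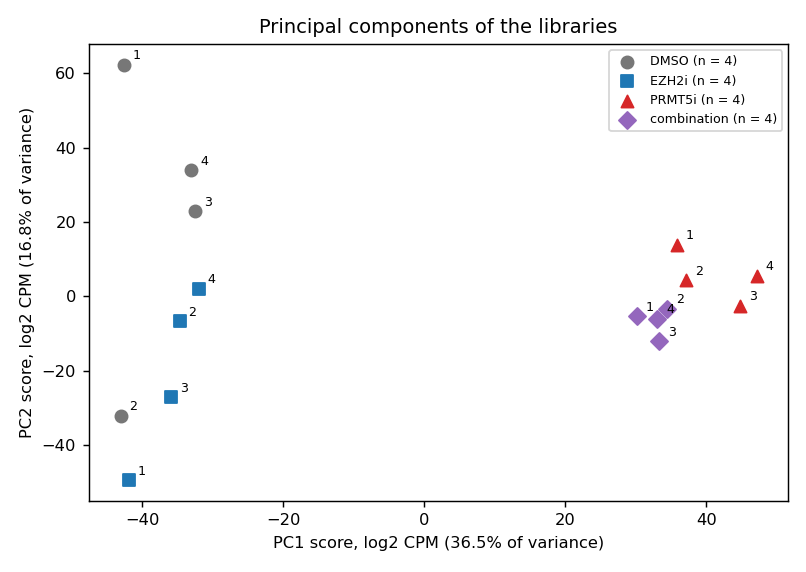
Scores of the 16 libraries on the first principal component (36.5% of the variance) and the second (16.8%), in log2 CPM, with replicate numbers beside the points. PRMT5i and combination libraries lie right of 30.2, and DMSO replicate 1 lies highest at 62.3.

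Levels of the 2 drug targets come first. EZH2 (ENSG00000106462.10; GRCh38 chromosome 7, 148807383 to 148884321, GENCODE v29) had 37.6 ± 10.7 CPM with DMSO, 48.3 ± 0.464 with EZH2i, 24.8 ± 1.36 with PRMT5i and 35.0 ± 0.943 in the combination (mean ± SD, n = 4). It fell with PRMT5i by 0.60 on the log2 scale (SE 0.16, adjusted p = 0.00659), and its change with EZH2i did not pass (log2 fold change 0.36, SE 0.16, adjusted p = 0.151). The DMSO spread comes from replicate 1, which had 21.5 CPM of EZH2. Without that library the combination against DMSO passed for EZH2 at −0.31, in place of −0.10 with adjusted p = 0.640, and with total counts only it was 0.01. The rise of EZH2 from PRMT5i to the combination, 0.50, did not pass in edgeR (adjusted p = 0.0942) and passed in DESeq2 at 0.49. PRMT5 (ENSG00000100462.15; chromosome 14, 22920511 to 22929585) had 116 ± 10.3, 115 ± 9.16, 119 ± 3.35 and 124 ± 5.14 CPM in the same order, and none of its changes passed in edgeR. An antisense gene, PRMT5-AS1, covers 27.1% of its exon bases on the opposite strand, so its level is uncertain to that extent. These mRNA levels do not measure the activity of either enzyme.

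EZH2i against DMSO compares cells under EZH2 inhibition alone with control cells. Of 35 splits of these 8 libraries into 4 and 4, 3 gave as many genes, the real one included. Chance is therefore not excluded for the number of genes called, as the section on flagged results describes. The chemokine gene CXCL10 (ENSG00000169245.5; chromosome 4, 76021117 to 76023497), an interferon target, fell from 7.46 ± 3.06 to 0.896 ± 0.0423 CPM (log2 fold change −3.06, SE 0.27, adjusted p = 1.39e-05). The low-affinity IgE receptor gene FCER2 fell from 22.7 to 9.35 CPM (−1.28, SE 0.16), and CHST2, which encodes a sulfotransferase, fell from 8.08 to 3.60 CPM (−1.17, SE 0.14). The proteoglycan gene VCAN fell from 7.92 to 3.26 CPM (−1.29, SE 0.24), and CD48 fell by 1.51 (SE 0.15), but a gene on the opposite strand covers 29.8% of its exon bases, so it is uncertain. NLRP12 fell by 1.22 (SE 0.36, adjusted p = 0.0453), a call lost with total counts only and without any 1 of the 8 DMSO and EZH2i libraries except DMSO replicate 2. The poly(A) polymerase gene FAM46C rose from 4.01 ± 1.13 to 13.7 ± 1.41 CPM (1.76, SE 0.16, adjusted p = 1.39e-05). XIRP1, an actin-binding gene of muscle (ENSG00000168334.8; chromosome 3, 39183210 to 39192596), rose from 4.12 to 13.8 CPM (1.75, SE 0.19, adjusted p = 1.21e-04). IGLL1, which encodes a surrogate light chain of B cell precursors, rose from 3.07 to 9.20 CPM (1.61, SE 0.27). PRG2, an eosinophil granule protein gene, rose from 162 to 555 CPM (1.78, SE 0.51, adjusted p = 0.0432), a call lost without DMSO replicate 3, DMSO replicate 4, EZH2i replicate 1 or EZH2i replicate 2. In replicate order it had 286, 244, 58.8 and 59.6 CPM with DMSO and 792, 826, 289 and 313 CPM with EZH2i. It thus rose both within replicates 1 and 2 and within replicates 3 and 4. C1orf186 rose by 1.61 (SE 0.38), a call lost without DMSO replicate 4 or EZH2i replicate 2. The largest overlap with a single other gene covers 43.0% of the exon bases of PRG2 and 19.3% of those of C1orf186, so both are uncertain. ECI2, a gene of fatty acid oxidation, rose most among protein-coding genes with at least 5 CPM in the higher group (2.21, SE 0.16). However, a single gene on the opposite strand covers 27.1% of its exon bases, which leaves the source of its reads uncertain.

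Of the 24 interferon-stimulated genes, 16 fell with EZH2i, none rose and 8 did not pass, with 21 lower when adjusted over the list alone. Their median log2 fold change was −0.66 (camera adjusted p = 3.09e-15, and adjusted p = 0.173 with an estimated correlation). The antiviral genes IFI6 (−0.85, SE 0.10) and MX2 (−0.92, SE 0.11) had the smallest p. All 6 tested markers of epithelial cells and fibroblasts rose, with a median of 1.08, among them the keratin gene KRT18 (0.70) and the collagen gene COL1A2 (1.98, SE 0.38, from 0.419 to 1.62 CPM). Their camera adjusted p was 2.43e-05, with adjusted p = 0.150 with an estimated correlation. Without DMSO replicate 3, DMSO replicate 4, EZH2i replicate 1 or EZH2i replicate 2, 3, 2, 3 and 3 of these 6 genes rose. In sterol synthesis 6 of 17 genes rose, including DHCR7 (0.51, SE 0.10), 10 when adjusted over the list alone (median 0.27, camera adjusted p = 2.43e-05, adjusted p = 0.150 with an estimated correlation). That count became 3 without DMSO replicate 3 or EZH2i replicate 3, and 2 without DMSO replicate 4 or EZH2i replicate 2. DNA replication genes had 6 of 34 higher, 8 when adjusted over the list alone (median 0.15, camera adjusted p = 6.19e-05, adjusted p = 0.173 with an estimated correlation), with 13 higher without DMSO replicate 2 and 3 without DMSO replicate 4. Examples are the transcription factor gene E2F8 (0.73, SE 0.12) and the ribonucleotide reductase gene RRM2 (0.51, SE 0.10).

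Monocyte and macrophage markers moved both ways with EZH2i. The transcription factor gene IRF8 fell from 315 to 215 CPM (−0.55, SE 0.07), the endotoxin receptor gene TLR4 rose (0.60), and in all 6 of 19 fell and 2 rose, or 9 and 3 when adjusted over the list alone (camera adjusted p = 0.0494, a call lost with GC correction, and adjusted p = 0.303 with an estimated correlation). Granulocyte markers had 3 of 11 higher, such as the myeloperoxidase gene MPO (0.89, SE 0.19), and 4 when adjusted over the list alone (median 0.52, camera adjusted p = 0.00760, adjusted p = 0.491 with an estimated correlation). The count of granulocyte genes was 7 without DMSO replicate 2 and 1 without DMSO replicate 3 or 4 or EZH2i replicate 1 or 2. Further lists passed camera with few single genes: the PRC2 subunits (JARID2 higher at 0.37, a call lost with no filter on low counts, median 0.18, and 4 genes higher without DMSO replicate 2), the stress response (2 of 15 lower, median −0.24), cytosolic ribosomal proteins (0 of 56 past the threshold in edgeR, median −0.18) and mitochondrially encoded proteins (median 0.64, 6 of 13 higher when adjusted over the list alone, and 11 over all genes without DMSO replicate 2). With an estimated correlation their adjusted p was 0.187, 0.494, 0.589 and 0.345. None of the 10 lists past camera with EZH2i stayed past with an estimated correlation.

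Developmental regulators, the class that PRC2 is best known to silence, did not move together with EZH2i. Only 19 of the 127 on the list were expressed enough to test. FOXA1 rose (1.08, SE 0.19, from 1.57 to 3.30 CPM), as did IRX3 (0.48) and IRX5 (0.69), POU4F1 fell (−1.67; a gene on the opposite strand covers 27.7% of its exon bases, so it is uncertain), and 15 did not pass. Their median was −0.15, their mean 0.00 and the direction of the test up (camera adjusted p = 0.767). The count of 3 higher became 1 without DMSO replicate 3, DMSO replicate 4, EZH2i replicate 1 or EZH2i replicate 2. The CDK inhibitor gene CDKN1C rose (1.29, SE 0.26, from 0.740 to 1.77 CPM), the other 4 tested genes of its list did not pass (median −0.05, mean 0.18, direction of the test up), and CDKN2A and CDKN2B had 0 counts in all 16 libraries, which places them under 3 counts per library.

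With EZH2i, 1259 of 16555 genes passed, 681 higher and 578 lower, and 242 of them changed by at least 1 on the log2 scale (175 higher, 67 lower). Scaled by total counts only, the split was 855 higher and 289 lower. Single libraries moved this count. It was 499 without DMSO replicate 4, 737 without DMSO replicate 3, 758 without EZH2i replicate 1, 728 without EZH2i replicate 2 and 4591 without DMSO replicate 2. DESeq2 called 2176 genes, and a fit with only these 2 groups called 135. The groups differed in spread, with chi-square per degree of freedom of 14.4 to 296 between DMSO pairs and 8.92 to 38.6 between combination pairs. The spread shared by all groups can therefore be too small for EZH2i against DMSO, and its adjusted p-values too low. It can be too large for the combination against PRMT5i.

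PRMT5i against DMSO changed more genes than EZH2i did, 5847 against 1259. The calcium-binding gene S100P (ENSG00000163993.6; chromosome 4, 6693069 to 6697170) fell from 11.8 ± 3.10 to 0.287 ± 0.0338 CPM (log2 fold change −5.35, SE 0.26, adjusted p = 6.48e-10). The secreted glycoprotein gene STC2 fell from 34.5 ± 4.89 to 1.96 ± 0.183 CPM (−4.13, SE 0.32, adjusted p = 5.84e-08), and INHBE, an inhibin subunit gene, fell by 3.73 on the log2 scale (SE 0.24). The nicotinic receptor gene CHRNA6 rose from 2.84 ± 1.24 to 39.5 ± 3.66 CPM (3.77, SE 0.24, adjusted p = 8.96e-09). The acid phosphatase gene ACPP (ENSG00000014257.15; chromosome 3, 132317367 to 132368298) rose from 11.2 ± 0.852 to 129 ± 13.0 CPM (3.53, SE 0.10, adjusted p = 1.34e-12), and MPEG1 rose by 3.65 (SE 0.36). The collagen gene COL24A1 (3.15, SE 0.18) and DTX4 (2.90, SE 0.45) rose as well, and NLRP12 (−3.40, SE 0.40) and the histone gene HIST3H2BB (−3.25, SE 0.18) fell.

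Genes of proliferation fell nearly throughout with PRMT5i. Of 34 DNA replication genes 31 fell and 0 rose in edgeR (median −1.14), of 27 mitosis genes 26 fell (median −1.08), and all 37 tested replication-dependent histone genes fell (median −1.71). Adjusted over the list alone, 32, 26 and 37 fell. The origin recognition gene ORC1 fell from 55.4 to 18.8 CPM (−1.55, SE 0.07, adjusted p = 5.32e-10), the mitotic kinase gene AURKB from 29.5 to 7.57 CPM (−1.96, SE 0.12), the topoisomerase gene TOP2A from 432 to 148 CPM (−1.54, SE 0.10), and the linker histone gene HIST1H1B from 587 to 162 CPM (−1.86, SE 0.11). Histone genes of this list are near-identical copies, so that single members are uncertain while the whole is less so. All genes with a HIST symbol, on the list or not, took 0.982 ± 0.114% of the counts with DMSO and 0.317 ± 0.0324% with PRMT5i. All 3 lists passed camera (adjusted p = 3.96e-24, 4.26e-18 and 2.93e-31). With an estimated correlation only replication stayed past (adjusted p = 0.00120), against adjusted p = 0.0516 with an estimated correlation for mitosis and adjusted p = 0.115 with an estimated correlation for histones.

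Stress response genes fell as well, 11 of 15, with 1 higher (median −1.60, 11 and 1 also when adjusted over the list alone). The pseudokinase gene TRIB3 fell from 227 to 45.9 CPM (−2.31, SE 0.15) and CHAC1, a glutathione-degrading enzyme gene, from 28.0 to 1.83 CPM (−3.92, SE 0.53), while the chaperone gene HSPA5 rose (1.04). The list's camera adjusted p was 1.19e-06, and adjusted p = 0.120 with an estimated correlation. Of 10 MHC class II genes 9 were higher and 1 lower (median 2.52, camera adjusted p = 2.17e-07, adjusted p = 0.00120 with an estimated correlation), HLA-DRA rising from 2.69 to 28.4 CPM (3.40, SE 0.16) and the class II transactivator gene CIITA from 1.27 to 6.31 CPM (2.32). Monocyte and macrophage markers had 11 of 19 higher and 2 lower, including the integrin gene ITGAM (1.47, SE 0.10, from 25.2 to 70.0 CPM) and S100A8 (2.13, SE 0.22). MLL self-renewal genes had 9 of 18 higher and 1 lower, such as HOXA5 (1.07, SE 0.11) higher and BCL2 (−0.59) lower. Immediate early genes had 2 of 13 higher and 6 lower, with the AP-1 subunit gene JUN falling by 1.04. These 3 lists passed camera (adjusted p = 0.00305, 0.00526 and 0.0415), with adjusted p = 0.115, 0.251 and 0.369 with an estimated correlation, and a block, for the replicate number or for replicates 1 and 2 against replicates 3 and 4, ended the call of the immediate early genes. Mitochondrially encoded genes had 6 of 13 higher (camera adjusted p = 0.00691, adjusted p = 0.448 with an estimated correlation), 11 without DMSO replicate 2, 2 without DMSO replicate 3 or 4, and 3 without PRMT5i replicate 3 or 4.

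The remaining lists did not pass camera with PRMT5i, though single members changed. In the PRMT family 6 of 13 fell and 1 rose, PRMT1 among the former (from 368 ± 35.6 to 252 ± 19.2 CPM, −0.55, SE 0.09, adjusted p = 2.17e-04), with 3 lower without DMSO replicate 4 or PRMT5i replicate 1. Among PRC2 subunits JARID2 rose (0.89, SE 0.08, adjusted p = 3.64e-07) and RBBP7 fell (−0.50, SE 0.06). P53 targets had 9 of 27 higher and 8 lower, the growth arrest gene BTG2 (1.22) among the former and the apoptosis gene BBC3, at 0.501 of its level with DMSO, among the latter. CDKN1A, the p21 gene, fell by 0.38 (SE 0.07). Interferon-stimulated genes had 7 of 24 higher and 5 lower, with 2 lower without DMSO replicate 4 or PRMT5i replicate 4 and 3 without PRMT5i replicate 3. Core spliceosome genes had 3 of 29 higher and 9 lower, SNRPB falling by 0.56, and their median of −0.05 turned to 0.01 with total counts only. Spliceosome genes higher numbered 8 without DMSO replicate 2, and 1 without DMSO replicate 4 or PRMT5i replicate 2, 3 or 4. Nucleolar and MYC targets had 2 of 20 higher and 8 lower, including NOP56 (−0.61, SE 0.08). Sterol synthesis genes had 4 of 17 lower (8 without DMSO replicate 2), developmental regulators 6 of 19 higher and 1 lower, MHC class I genes 2 of 12 higher and 4 lower, and BCL2 family genes 4 of 14 higher and 3 lower. The ribosomal protein list had 1 of 56 lower. Markers of other lineages gave 2 higher and 2 lower of 11 for granulocytes, 3 and 1 of 7 for T and NK cells, 2 and 1 of 7 for B cells, 3 and 0 of 6 for epithelial cells and fibroblasts, 1 and 1 of 4 for megakaryocytes (median 0.21, mean −0.13), and for erythroid cells the only tested gene, EPOR, fell by 1.06 (SE 0.12).

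PRMT5i changed 5847 of 16555 genes, 2824 higher and 3023 lower, and 1564 by at least 1 on the log2 scale (813 higher, 751 lower). By fry, 21 of the 27 lists moved on balance one way.

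The combination against DMSO gave 5990 genes, 2920 higher and 3070 lower, with 925 and 517 of them changed by at least 1 on the log2 scale. Total counts only shifted the median of all genes by 0.13 in this comparison and gave 3897 higher and 2021 lower, so that small changes here are relative to the scaling. Several genes named for PRMT5i alone changed here too: S100P (−5.00, SE 0.25), STC2 (−3.45), INHBE (−3.23), NLRP12 (−3.13), CHRNA6 (3.85, SE 0.24), ACPP (3.38, SE 0.10) and MPEG1 (3.05). ORM1, an acute phase protein gene with a near-identical copy and so uncertain, fell by 3.05. The kinase gene RPS6KA2 fell from 12.9 ± 2.33 to 1.64 ± 0.426 CPM (−2.99, SE 0.20, adjusted p = 3.24e-08). SLITRK6, a neuronal membrane protein gene, rose from 0.622 ± 0.219 to 7.35 ± 0.836 CPM (3.59, SE 0.24, adjusted p = 3.04e-08). SERPINB2 (4.93, SE 0.35) shares 19.9% of its exon bases with SERPINB10 and MT1H (3.61) has near-identical metallothionein copies, so both are uncertain.

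Interferon-stimulated genes rose in the combination, opposite to EZH2i alone. Of 24 genes 20 rose, 0 fell in edgeR and 4 did not pass, or 21 and 1 when adjusted over the list alone (median 0.78, camera adjusted p = 1.98e-09, adjusted p = 0.184 with an estimated correlation). IFI6 rose from 42.0 to 80.5 CPM (0.94, SE 0.10) and MX2 from 28.8 to 59.0 CPM (1.03, SE 0.11). DNA replication genes had 28 of 34 lower (median −0.70), mitosis genes 21 of 27 (median −0.47, and 14 with total counts only) and histone genes 36 of 37 (median −1.19). Adjusted over the list alone these were 28, 22 and 37, with adjusted p = 0.00851, 0.184 and 0.184 with an estimated correlation. MHC class II genes had 9 of 10 higher and 1 lower (mean 1.64, adjusted p = 0.00851 with an estimated correlation), and stress response genes 1 of 15 higher and 11 lower (median −1.23, adjusted p = 0.184 with an estimated correlation). Also past camera were MLL self-renewal genes (10 of 18 higher, 1 lower, for example HOXA5 at 1.26 and RUNX2 at 0.97), epithelial and fibroblast markers (5 of 6 higher) and mitochondrially encoded genes (11 of 13 higher, 7 without DMSO replicate 3 or combination replicate 2, 6 without DMSO replicate 4). With an estimated correlation these 3 had adjusted p = 0.184, 0.184 and 0.322. Cytosolic ribosomal protein genes had 31 of 56 lower, for example RPS27 (−0.49), but 14 with total counts only, 18 without combination replicate 1 and 16 without combination replicate 2 (median −0.29, adjusted p = 0.375 with an estimated correlation).

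Lists that did not pass camera in the combination against DMSO again held changed members. PRC2 subunits had 2 of 11 higher and 3 lower, JARID2 rising by 1.08. Their median was −0.10 and turned to 0.01 with total counts only, their mean was 0.03 and the direction of the test down. PRMT family genes had 1 of 13 higher and 5 lower, PRMT1 falling by 0.61 (SE 0.09). That count of 5 was 3 without DMSO replicate 4, EZH2i replicate 3, PRMT5i replicate 4 or combination replicate 4, 2 without combination replicate 1 or 3, and 1 with total counts only. Spliceosome genes had 3 of 29 higher and 8 lower (10 higher without DMSO replicate 2). Their median of −0.05 turned to 0.08 with total counts only, their mean was 0.02 and the direction of the test down. Nucleolar and MYC targets had 2 of 20 higher and 9 lower, while the number lower was 3 with total counts only and 4 without combination replicate 4. P53 targets had 7 of 27 higher and 5 lower, developmental regulators 7 of 19 higher and 3 lower, monocyte markers 8 of 19 higher and 4 lower, immediate early genes 2 of 13 higher and 6 lower, and BCL2 family genes 3 of 14 higher and 5 lower, or 3 lower without DMSO replicate 4 or combination replicate 2, 3 or 4.

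The combination against PRMT5i asks what EZH2 inhibition adds in PRMT5-inhibited cells, the question that the title of the series raises. RGS1, a regulator of G protein signalling (ENSG00000090104.11; chromosome 1, 192575727 to 192580031), rose from 8.65 ± 1.68 to 33.9 ± 2.74 CPM (log2 fold change 1.97, SE 0.24, adjusted p = 2.91e-04). XIRP1 rose from 0.996 ± 0.188 to 3.96 ± 0.565 CPM (1.98, SE 0.22, adjusted p = 1.74e-04), the antiviral gene RSAD2 from 13.8 ± 3.06 to 36.0 ± 3.80 CPM (1.39, SE 0.17, adjusted p = 3.86e-04), and the angiopoietin gene ANGPT1 from 17.4 ± 3.05 to 43.2 ± 3.89 CPM (1.31, SE 0.26, adjusted p = 0.00891). The laminin receptor gene ITGA6 fell from 5.76 ± 0.571 to 2.11 ± 0.236 CPM (−1.45, SE 0.16, adjusted p = 2.36e-04) and the angiotensinogen gene AGT from 5.66 to 2.66 CPM (−1.09, SE 0.16). VCAN (−1.28, SE 0.24) and CD48 (−1.64, SE 0.15, with the doubt given above) fell again. ECI2 rose by 2.76 (SE 0.15) with the same doubt about its reads as above. In all 688 genes passed, 482 higher and 206 lower (748 and 121 with total counts only), and 107 and 28 of the 688 changed by at least 1 on the log2 scale. The count was 263 without PRMT5i replicate 3, 327 without PRMT5i replicate 4, 393, 373 and 438 without combination replicate 1, 2 and 4, and 1067 in DESeq2. A fit with only these 2 groups called 2099.

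Proliferation genes were higher in the combination than with PRMT5i alone. Of 34 replication genes 17 rose and none fell, 26 when adjusted over the list alone (median 0.41), and of 27 mitosis genes 19 rose, 26 when adjusted over the list alone (median 0.59). The replication helicase gene CDC45 rose from 13.2 to 20.8 CPM (0.66, SE 0.08), the kinetochore gene CENPF from 98.7 to 168 CPM (0.77, SE 0.09) and the spindle checkpoint gene BUB1 from 54.5 to 82.2 CPM (0.59, SE 0.08), against 47.2, 200 and 100 CPM with DMSO. Both lists stayed past with an estimated correlation (adjusted p = 0.00103 and 0.0110). Of 37 histone genes 13 rose, 31 when adjusted over the list alone (median 0.48, camera adjusted p = 1.15e-20, adjusted p = 0.168 with an estimated correlation). All genes with a HIST symbol, on the list or not, took 0.460 ± 0.0432% of the counts. Numbers of called genes on the 3 lists fell when a library was left out. Without PRMT5i replicate 3, PRMT5i replicate 4 or combination replicate 1, 9, 10 and 10 replication genes and 7, 9 and 10 mitosis genes passed, and 12 mitosis genes passed without combination replicate 2. The count of histone genes was 8 without EZH2i replicate 3 or PRMT5i replicate 1, 5 without PRMT5i replicate 2, 1 without PRMT5i replicate 3 or 4, 3 without combination replicate 1 or 4 and 2 without combination replicate 3, while the median of the list stayed between 0.40 and 0.54 in these 8 fits.

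Interferon-stimulated genes rose too when EZH2i was added to PRMT5i, 18 of 24 with none lower, and 20 when adjusted over the list alone (median 0.61, adjusted p = 0.0277 with an estimated correlation). HERC5, a ligase gene for ISG15, rose from 14.5 to 28.6 CPM (0.98, SE 0.11). The number was 9 without PRMT5i replicate 3 or 4, 11 without combination replicate 1 and 10 without combination replicate 2. MHC class II genes fell, 4 of 10 and 6 when adjusted over the list alone (median −0.62, adjusted p = 0.00103 with an estimated correlation), HLA-DRA from 28.4 to 13.8 CPM and HLA-DMA from 6.18 to 2.99 CPM (both −1.04, SE 0.14). Monocyte markers fell, 5 of 19 and 7 when adjusted over the list alone (median −0.31, adjusted p = 0.0265 with an estimated correlation), such as S100A8 (−1.69, SE 0.21) and IRF8 (−0.38, SE 0.07), with 3 lower without PRMT5i replicate 3 or 4 or combination replicate 1 or 2. Other lists past camera had few single calls: stress response (1 of 15 higher, median 0.27, with unlike levels between the combination libraries as given for the interaction below), sterol synthesis (median 0.19), ribosomal proteins (median −0.20), PRC2 subunits (median 0.12) and T and NK cell markers (CD3D higher at 1.01, median 0.57). Their adjusted p was 0.323, 0.117, 0.176, 0.150 and 0.150 with an estimated correlation. P21 gene CDKN1A rose by 0.41 (SE 0.07), back to 228 CPM from 172, against 224 CPM with DMSO.

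**Figure D2:**
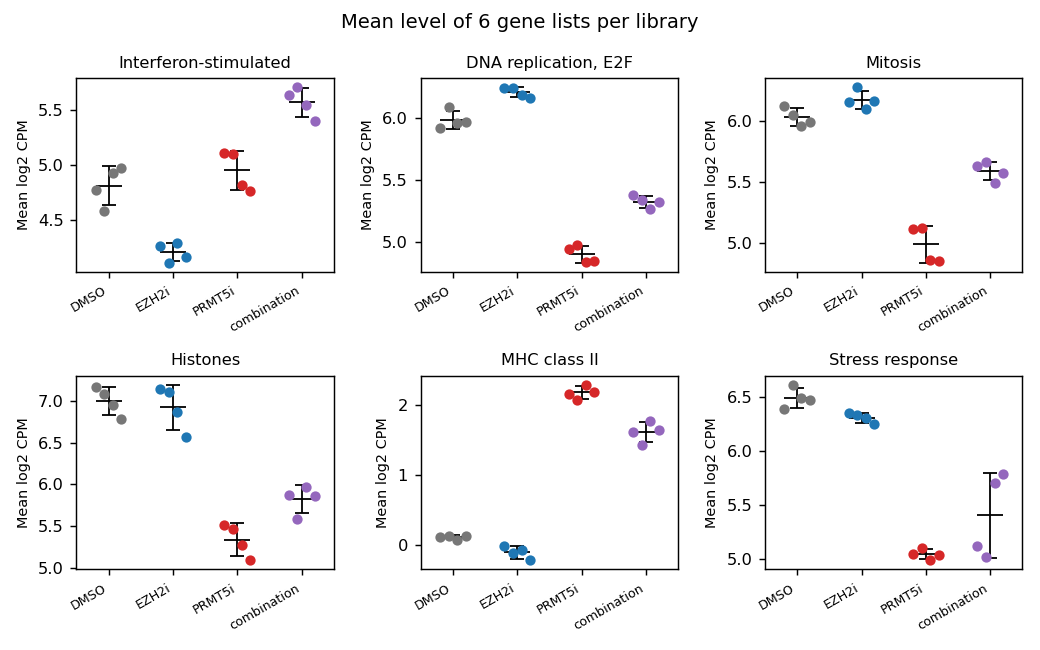
Mean log2 CPM of 6 gene lists in each library (points), with the group mean and SD of 4 libraries (bars). Replication, mitosis and histone levels fall with PRMT5i and lie higher in the combination, while interferon-stimulated genes are lowest with EZH2i (4.11 to 4.30) and highest in the combination (5.40 to 5.71).

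A set of 280 genes was lower with PRMT5i and higher again when EZH2i was added, 9.26% of the genes that PRMT5i lowered and 58.1% of those that rose with the added EZH2i. Besides XIRP1, RGS1 and ANGPT1, these included the signalling adaptor gene TRAF1 (PRMT5i against DMSO −1.70, then 1.11), the growth factor antagonist gene SPRY1 (−1.62, then 1.04), the meiotic inhibitor gene FBXO43 (−1.50, then 1.01) and the T cell receptor subunit gene CD3D (−1.11, then 1.01). The cystine transporter gene SLC7A11 (−3.20, then 1.35) lost its rise without combination replicate 4 (1.06), PRMT5i replicate 3 (1.26) or PRMT5i replicate 4 (1.34). The median of the 280 was −1.08 with PRMT5i and 0.60 with the added EZH2i, and 164 were still lower than with DMSO in the combination, whereas 6 were higher. The replication, mitosis and histone lists held 49 of them. EZH2i alone raised 64 of the 280 and lowered 6, and 10 passed the interaction.

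Independent lists of the same lengths would share 88.0 genes, and unchanged groups that shared the PRMT5i libraries gave at most 1 in 20 simulations. Those groups hold no changed genes, so few calls could overlap. The simulations cannot show what shared libraries do among genes that PRMT5i changes. With the PRMT5i libraries divided between the comparisons, 189 genes were shared against 43.3 for independent lists, and 35 against 10.4 the other way round. The mirror set, higher with PRMT5i and lower with the added EZH2i, held 131 genes against 35.1. Genes that moved the same way in both numbered 66 higher against 82.2 and 8 lower against 37.6. The count of 280 was 106 and 121 without PRMT5i replicate 3 and 4, and 158, 169 and 180 without combination replicate 1, 2 and 4. Fold changes of the 2 comparisons correlated across genes at −0.327 (simulated −0.485), with covariance −0.0883 against −0.0414 simulated.

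**Figure D3:**
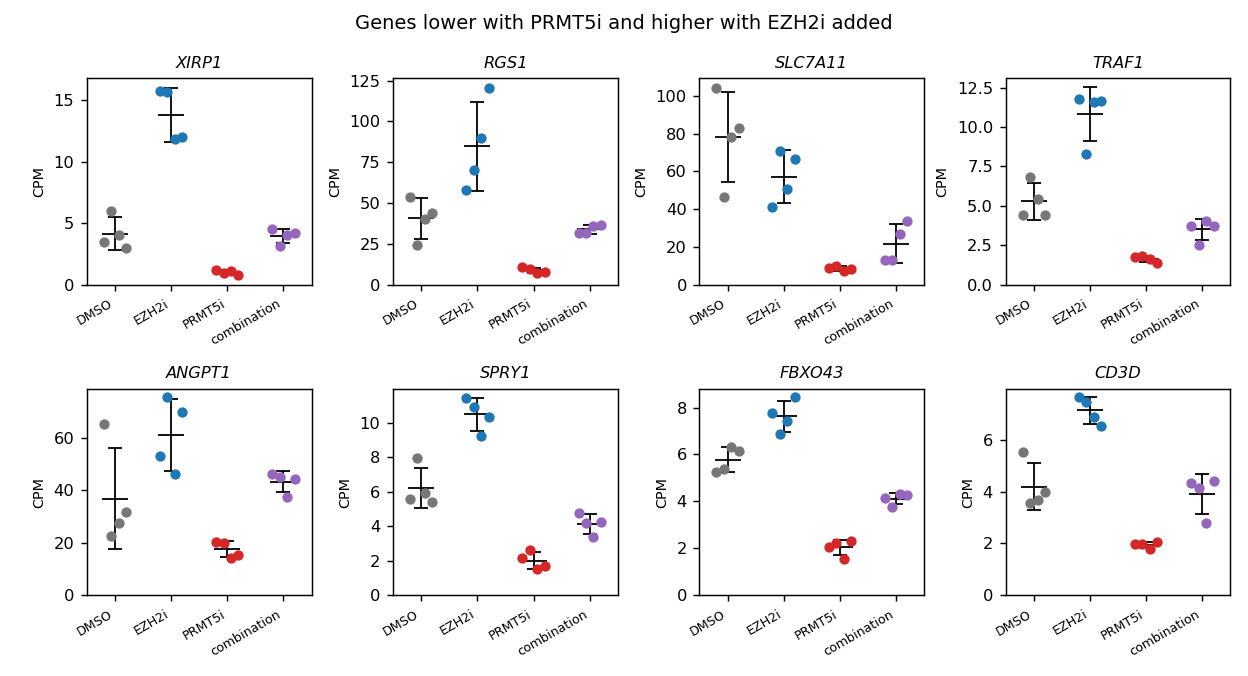
CPM per library (points) with group mean and SD of 4 libraries (bars) for the 8 genes lower with PRMT5i and higher with EZH2i added that had the largest smaller fold change. They were taken from protein-coding genes with a mean of at least 5 CPM in any of the 4 groups. RGS1 had 8.65 CPM with PRMT5i and 33.9 CPM in the combination.

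The single inhibitors were also compared with each other. A set of 108 genes rose with EZH2i and fell with PRMT5i, against 124 for independent lists. Simulations of unchanged groups that shared the DMSO libraries gave 0, but they hold no changed genes whose calls could overlap. XIRP1 (1.75 and −2.03), the von Willebrand factor gene VWF (1.56 and −1.85), RGS1 (1.07 and −2.22), TRAF1 (1.04 and −1.70), the neuronal enolase gene ENO2 (0.86 and −1.07), C6orf223 (0.85 and −1.59) and the protease inhibitor gene A2M (0.80 and −1.05) belong to it, as does C1orf186 (1.61 and −1.46, uncertain as above), and 64 of the 108 were among the 280 above. The number was 47 without DMSO replicate 4, 63 without DMSO replicate 3, 70 without EZH2i replicate 2 and 213 without DMSO replicate 2. With the DMSO libraries divided it was 28 against 23.2, 77 against 51.3, 175 against 186 and 19 against 16.9. Genes that rose with both numbered 257 against 116, those that fell with both 206 against 106, and those lower with EZH2i and higher with PRMT5i 103 against 98.6. The fold changes of the single inhibitors correlated at 0.268 across genes, which are not replicates, below the 0.497 that shared DMSO libraries alone gave. The covariance was 0.0862 against 0.0433 simulated, and divided DMSO libraries gave correlations of 0.186, −0.0131, 0.0177 and 0.140.

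The combination against EZH2i repeats the PRMT5i comparison in EZH2-inhibited cells and shares no library with it. It gave 4633 genes, 2221 higher and 2412 lower, with 682 and 465 changed by at least 1 on the log2 scale. Of these, 1598 were higher in both comparisons (379 for independent lists), 1889 lower in both (440), and 1 and 5 moved in opposite ways. Fold changes correlated at 0.746 across genes. Likewise EZH2i against DMSO and the combination against PRMT5i shared 178 higher genes (19.8 for independent lists) and 83 lower (7.19), and 1 and 21 moved in opposite ways, with a correlation of 0.335. Interferon-stimulated genes were higher in the combination than with EZH2i for 21 of 24 (median 1.30, adjusted p = 0.0664 with an estimated correlation). Replication genes were lower for 33 of 34 (median −0.89, adjusted p = 0.00130 with an estimated correlation), histone genes for 37 of 37, mitosis genes for 22 of 27, immediate early genes for 8 of 13 and sterol synthesis genes for 7 of 17. These last 4 lists each had adjusted p = 0.0985 with an estimated correlation. MHC class II genes were higher for 9 of 10 (median 2.03, adjusted p = 0.00130 with an estimated correlation).

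For 48 genes the effect of EZH2i differed with and without PRMT5i, 42 with a higher value in PRMT5-inhibited cells and 6 with a lower one. Of the 48, 19 are among the 24 interferon-stimulated genes. CXCL10 had the largest interaction among genes with at least 5 CPM in a group (3.60, SE 0.36, adjusted p = 1.43e-04), from a fall with EZH2i alone to 4.17 ± 0.745 CPM with PRMT5i and 6.08 ± 0.820 CPM in the combination. IFI6 (1.40, SE 0.14, adjusted p = 1.43e-04), the oligoadenylate synthase gene OAS1 (1.39, SE 0.14), MX2 (1.38, SE 0.16), EPSTI1 (1.65, SE 0.20) and MX1 (1.74, SE 0.23, adjusted p = 0.00146) also had a higher value in PRMT5-inhibited cells. Against DMSO they differ from CXCL10, which fell with PRMT5i (−0.84, adjusted p = 0.00946) and did not pass in the combination (−0.30, adjusted p = 0.326). IFI6, MX2 and MX1 rose with PRMT5i (0.39, 0.57 and 0.77), OAS1 (0.19) and EPSTI1 (0.33) did not pass there, and all 5 rose in the combination. IFITM1 (1.55, SE 0.19) shares 32.5% of its exon bases with IFITM2 and is uncertain. MX1 had 41.2 ± 5.47 CPM with DMSO, 20.4 ± 2.77 with EZH2i, 70.1 ± 15.9 with PRMT5i and 116 ± 18.0 in the combination. The 6 lower genes were FAM46C (−1.30), TSPAN9 (−1.64), CXCR3 (−1.48), PDGFRB (−1.24), ADAMTS10 (−1.05) and SIGLEC6 (−0.86). TSPAN9, CXCR3, ADAMTS10 and SIGLEC6 were chosen after their values were seen.

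The list of interferon-stimulated genes had a median interaction of 1.34, with 23 of 24 higher when adjusted over the list alone, and passed with a preset and with an estimated correlation (camera adjusted p = 1.65e-50, adjusted p = 0.00914 with an estimated correlation). Mitosis genes had a median of 0.50 and histone genes of 0.58, with 22 of 27 and 24 of 37 higher when adjusted over the list alone. Over all genes 1 replication gene passed, CDC45 (0.64), and with DESeq2 4 mitosis and 3 histone genes passed. With an estimated correlation these lists had adjusted p = 0.0992 for mitosis, 0.243 for histones and 0.103 for replication. Stress response genes had a median of 0.55 (adjusted p = 0.143 with an estimated correlation). Their mean log2 CPM was 5.12 and 5.01 in combination replicates 1 and 2, near the 4.98 to 5.10 with PRMT5i, and 5.70 and 5.79 in replicates 3 and 4, so the group values for this list join unlike libraries. Camera also passed granulocyte markers (−0.39), epithelial and fibroblast markers (−0.40), MHC class II (−0.42), mitochondrially encoded genes (−0.38), MHC class I (0.11) and ribosomal proteins (−0.03), with adjusted p = 0.489, 0.325, 0.117, 0.489, 0.489 and 0.636 with an estimated correlation. The number of genes with an interaction was 28 without PRMT5i replicate 3, 29 without PRMT5i replicate 4, 31 without EZH2i replicate 2 and 124 without DMSO replicate 2, and DESeq2 gave 113.

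**Figure D4:**
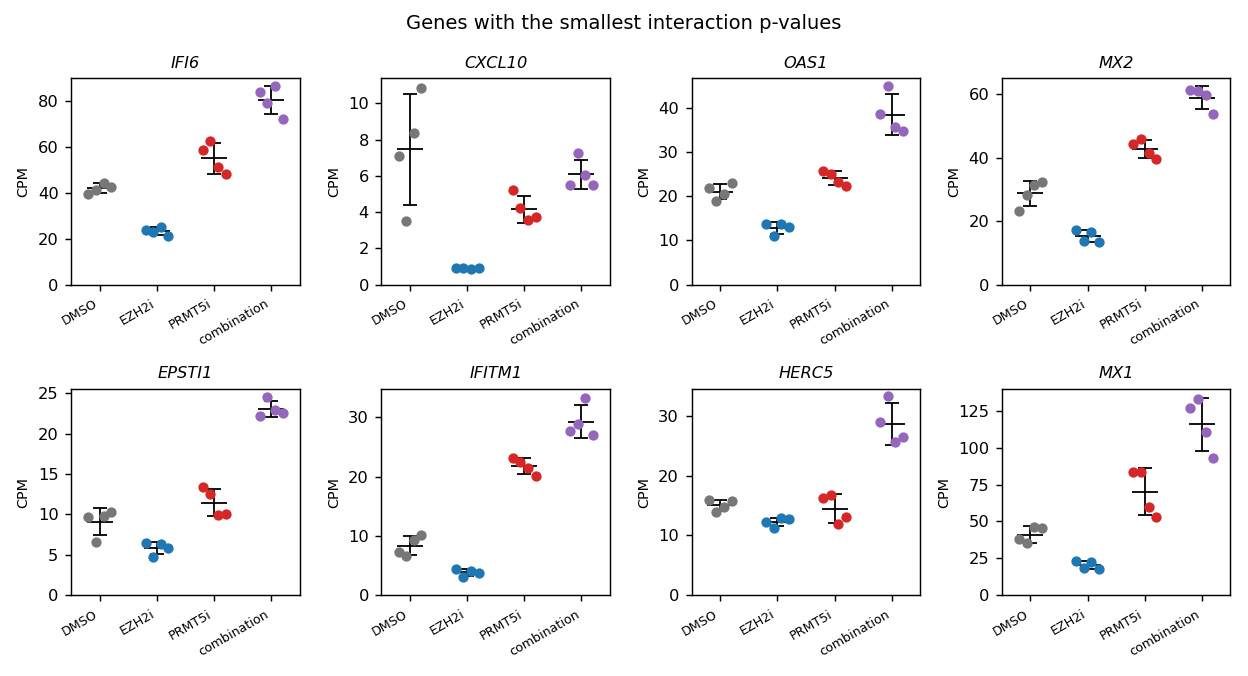
CPM per library (points) with group mean and SD of 4 libraries (bars) for the 8 genes with the smallest p of the interaction. MX1 falls from 41.2 CPM with DMSO to 20.4 CPM with EZH2i and reaches 116 CPM in the combination.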

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

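Of the tests below, those on labels, gene length, interferon beta mRNA, the fit without DMSO replicates 1 and 2, the block of replicate pairs and the other splits of the libraries were chosen only after the result was seen, and so was the GC correction itself, while the bound for the GC test of the DMSO libraries was written before its result. The label and length tests were widened to all 4 DMSO libraries after their first results.

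In a group of 4 libraries, a library counts as standing apart when its gap to the nearest other, divided by the range of the 4, exceeds Dixon's critical value, and that quotient is given below. Chance flags about 1 in 20 groups. Here 1 of 52 library measures and 28 of 584 groups of gene values passed, which is near that rate, and 5 of them lie in DMSO replicate 1. The library measure is how strongly the deviation from the group follows gene length, in which PRMT5i replicate 1 stood apart (quotient 0.934).

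DMSO replicate 1 stood apart for EZH2 (0.938, at 21.5 CPM against 42.9 in the mean of the other 3), EGR1 (0.941), RRM2 (0.916, at 104 CPM against 154), ECI2 (0.856) and DDIT3 (0.831). DMSO replicate 2 stood apart for E2F8 (0.909), MT-ND1 (0.905) and DHCR7 (0.832), and DMSO replicate 4 for GZMB (0.883) and GP1BA (0.872). Among EZH2i libraries these were replicate 1 for ATF3 (0.857), replicate 2 for TRAF1 (0.945) and replicate 4 for PAX5 (0.843). Among PRMT5i libraries they were replicate 1 for TLR4 (0.965), HOXA5 (0.883) and COL1A2 (0.841), replicate 2 for BID (0.937) and RPS27 (0.916), and replicate 3 for ATF3 (0.859), PAX5 (0.857) and CHST2 (0.839). In the combination they were replicate 1 for HLA-DQB1 (0.844), replicate 2 for CD48 (0.8292), replicate 3 for GP1BA (0.925), CD7 (0.839) and CD3D (0.831), and replicate 4 for A2M (0.945) and HIST3H2BB (0.883).

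The number of genes called for EZH2i against DMSO depends on which DMSO library is left out, from 499 without replicate 4 to 4591 without replicate 2. A GC trend between libraries does not account for the whole of this. Without DMSO replicate 2 the count rose from 1259 to 4591 before GC correction and from 2843 to 5261 after it, a ratio of 1.85, and with each of the 8 DMSO and EZH2i libraries left out in turn the range was 1534 to 5261 after correction. The correction thus lessened the dependence and did not remove it. A block of replicates 1 and 2 against replicates 3 and 4 did not remove it either, with 1533 genes from all libraries, 612 without DMSO replicate 4 and 5186 without DMSO replicate 2. No DMSO library scored like an EZH2i library (highest 0.182, lowest EZH2i library 0.768), which argues against a wrong label, and the correlation of the deviations with gene length was at most −0.0470 in size, which argues against a length bias as degraded RNA gives. Another difference in how the DMSO or EZH2i cultures or libraries were handled stays open and may be the source, and no biological explanation was tested. Of the 35 splits of these 8 libraries 3 gave as many genes as the real 1259, and the highest other split, DMSO replicates 1, 3 and 4 with EZH2i replicate 4, gave 4877, which points to a structure of the samples, so chance is not excluded for this count, nor for its 10 gene lists (3 of 35 splits, highest other 10). With the block 3 of 35 splits gave as many as the real 1533 (highest other 5597), so chance is not excluded there. After GC correction that same split of DMSO replicates 1, 3 and 4 with EZH2i replicate 4 gave 1603. Of the 35 splits 1 then gave as many as the real 2843 (highest other 1890). The correction was chosen after seeing the data, and the versions without it did not pass, so chance is not excluded for the count.

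The effect of EZH2i differed with and without PRMT5i for 48 genes, by a test of the difference itself. Among the genes named in the text these are CXCL10 (3.60), MX1 (1.74), EPSTI1 (1.65), IFITM1 (1.55), RSAD2 (1.499), IFI6 (1.40), OAS1 (1.39), MX2 (1.38), HERC5 (1.27), HIST3H2BB (1.37), DDIT3 (0.86), CDC45 (0.64), ISG15 (1.21), FAM46C (−1.30), PDGFRB (−1.24), TSPAN9 (−1.64), CXCR3 (−1.48), ADAMTS10 (−1.05) and SIGLEC6 (−0.86). Of 100 splits of the libraries, 2 gave as many genes with an interaction, the real one included, and the highest other gave 3294. These splits mix libraries with and without PRMT5i, so they ask about any treatment effect and cannot decide on chance for the 48 interactions. For the same reason the 3294 do not show a structure of the samples beyond treatment. Of the 100 splits 7 gave as many as the 11 gene lists (highest other 12), so chance is not excluded for that number.

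Interferon-stimulated genes fell with EZH2i alone and rose when EZH2i was added to PRMT5i. The tables argue against 2 technical sources: 21 of the 24 genes passed the interaction after GC correction, and 21 without DMSO replicates 1 and 2, against 19 with all libraries. A candidate explanation for the rise is more interferon beta in the combination. IFNB1 had 0.409 ± 0.0762 CPM there, 0.212 ± 0.0585 with PRMT5i, 0.169 ± 0.0455 with EZH2i and 0.262 ± 0.0466 with DMSO, with an exact permutation p = 0.0286 for the combination against PRMT5i, the smallest that 4 against 4 libraries can give, but p = 0.0571 for EZH2i against DMSO, which does not pass, so the fall with EZH2i alone is left without an explanation. These levels rest on 5 to 24 counts per library, and mRNA does not show that the protein was made, so this is a hypothesis found and tested on the same data.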

How the results depend on the processing

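The GC correction, the fit to protein-coding genes, the fit without DMSO replicates 1 and 2 and the block of replicate pairs were chosen after seeing the data. No call of a named gene or list changed direction in the settings where these were compared, while some values that were not called changed sign. The fits with limma-voom, the stricter filter, protein-coding genes, only the groups compared and without DMSO replicates 1 and 2 were not compared in this way. With RLE size factors, limma-voom, the stricter filter, protein-coding genes and total counts only, the 8 counts of genes stayed within 1.5 times their values. With no filter 61 genes rose with EZH2i and fell with PRMT5i. DESeq2 gave 2176 genes for EZH2i against DMSO (1196 of the 1259 kept), 1067 for the combination against PRMT5i, 113 with an interaction and 172 opposed between the single inhibitors. With only the groups compared, EZH2i against DMSO gave 135 and the combination against PRMT5i 2099. GC correction gave 2843 and 1256 in these comparisons, 105 with an interaction, 490 lower with PRMT5i and higher with EZH2i added, and 242 opposed. Without DMSO replicates 1 and 2, EZH2i against DMSO gave 2418 and the combination against PRMT5i 1358, with 83, 432 and 177 in the other counts and a correlation between single inhibitors of 0.443. The cause was not tested.

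A log2 fold change of at least 1 left 242, 1564, 1442, 135 and 1147 genes (EZH2i, PRMT5i and combination against DMSO, combination against PRMT5i and against EZH2i), 28 lower with PRMT5i and higher with EZH2i added, and 14 opposed, as a smaller set by construction. Adjusted p under 0.01 left 301 for EZH2i, 3854 for the combination against DMSO, 230 and 2843 for the combination against PRMT5i and EZH2i, 26 with an interaction, 96 lower and then higher, and 31 opposed. With an estimated correlation 0, 2, 2, 5, 2 and 1 gene lists passed in the 5 comparisons and the interaction, against 10, 9, 10, 11, 12 and 11 with the preset, and fry gave 21 for PRMT5i, 20 for the combination against DMSO and 5 for the interaction.

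Leaving out 1 library gave 499 (DMSO replicate 4) to 4591 (DMSO replicate 2) genes for EZH2i against DMSO, 263 (PRMT5i replicate 3) to 1011 (DMSO replicate 1) for the combination against PRMT5i, 28 (PRMT5i replicate 3) to 124 (DMSO replicate 2) with an interaction, 106 (PRMT5i replicate 3) to 371 (DMSO replicate 1) lower and then higher, 47 (DMSO replicate 4) to 213 (DMSO replicate 2) opposed, and 7 (DMSO replicate 3) to 13 (EZH2i replicate 1) gene lists for the interaction. PRMT5i against DMSO stayed between 4898 and 6853, the combination against DMSO between 5122 and 7110, and against EZH2i between 3714 and 5565. Of 2088 calls of named genes in these fits 1931 were unchanged in side and direction, 152 lost significance, 1 gained it and 4 values of genes not called moved.

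No pairing of the libraries by single replicate number was seen, since 5 of 16 matched best a library of their own number. That match used values without GC correction, so a GC trend could hide a pairing. Replicates 1 and 2 do differ from 3 and 4 in 263 genes. A block for these pairs gave 1533, 5987, 6207, 908 and 4844 genes in the 5 comparisons in the order above, 69 with an interaction, 365 lower and then higher, and 158 opposed, all within 1.5 times their values. It changed none of the 253 calls of named genes, while 2 calls of gene lists were lost (immediate early genes with PRMT5i, erythroid markers in the combination against EZH2i), 1 was gained (epithelial and fibroblast markers in the combination against PRMT5i) and 1 value moved. A block for the replicate number gave 1430 genes for EZH2i against DMSO and 857 for the combination against PRMT5i and changed none of the 253 calls of named genes. The block for the replicate number lost and gained the same 3 list calls. GC correction ended 2 of 253 calls of named genes and 2 list calls (monocyte markers with EZH2i, erythroid markers in the combination against EZH2i). It added 8 list calls: mitosis, MHC class I and nucleolar genes with EZH2i, sterol synthesis with PRMT5i, epithelial markers in the combination against PRMT5i, p53 targets in the combination against EZH2i, and nucleolar and sterol synthesis genes in the interaction.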

Other observations

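The tests on shared PRMT5i libraries, on a uniformly weaker effect, on replicate pairs and on other splits of the libraries were chosen only after the result was seen, as was the GC correction, while the bound of its test was written before its result.

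Stress response genes differed between the combination libraries. Mean log2 CPM of the list was 5.12, 5.01, 5.70 and 5.79 in combination replicates 1 to 4, against 4.98 to 5.10 with PRMT5i, 6.25 to 6.36 with EZH2i and 6.39 to 6.62 with DMSO. CHAC1, a glutathione-degrading enzyme gene, had 1.31, 0.762, 7.22 and 8.87 CPM in these libraries, STC2 1.73, 1.32, 4.94 and 4.80 CPM, and SLC7A11 13.2, 12.9, 27.1 and 33.5 CPM. ASNS had 38.1, 36.7, 74.1 and 84.4 CPM, and a single other gene shares 44.6% of its exon bases, which leaves its level uncertain. This division was noticed after the values were seen. It falls between the same replicate numbers as the 263 genes that differ between replicates 1 and 2 and replicates 3 and 4, but 0 of the 15 stress genes passed for that term over all groups. Replication, mitosis and histone lists were lower in replicates 3 and 4 by camera (adjusted p = 3.20e-04, 2.36e-09 and 8.68e-14), with 1, 3 and 0 single genes lower and adjusted p = 0.0502, 0.0707 and 0.429 with an estimated correlation. Epithelial, granulocyte, sterol synthesis, MHC class I and interferon-stimulated lists were lower too (camera adjusted p = 0.00155 to 0.0487). Ribosomal proteins and monocyte markers were higher (camera adjusted p = 5.02e-07 and 0.00598). None of these lists passed with an estimated correlation. Of 100 splits of each group into 2 and 2 libraries, 2 gave as many as the 263 genes, the real one included, and the highest other gave 739. The division was looked for after seeing the data, so that share does not exclude chance for the number. The split with 739 genes points to a further structure of the samples. DMSO replicates 1 and 4 and EZH2i replicates 2 and 4 stood together in it. Their deviations correlated with GC content at −0.456 to −0.138, against 0.0260 to 0.467 in the other DMSO and EZH2i libraries. PRMT5i and combination libraries were not parted by this sign. For DMSO and EZH2i libraries alone this split gave 1093 genes, and 0 after GC correction. A GC trend is therefore a candidate source, but the split with 739 genes was not rerun after that correction. The source of the 263 genes is open.

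Replication, mitosis and histone genes were lower with PRMT5i and partly back when EZH2i was added. For all genes lower with PRMT5i and higher with EZH2i added, the tables argue against shared PRMT5i libraries as the whole cause. With these libraries divided, the overlap was 4.36 and 3.38 times that of independent lists. The listed genes were not counted apart in that test, so it cannot decide for them. GC correction left 48 of the 49 listed genes called, which argues against a GC trend as the whole cause. A uniformly weaker effect of PRMT5i in the presence of EZH2i, as less drug action may give, stays open: the median ratio of the PRMT5i effects with and without EZH2i was 0.664 for the listed genes, 0.709 for the 679 other lowered genes and 0.768 for raised genes, and listed minus raised genes gave a difference of −0.104 with a bootstrap SE of 0.0200, and the bound was 0.1. The condition on that SE was added after the value was seen, and selection of genes by the effect without EZH2i can lower such ratios. Genes chosen by the effect with EZH2i gave inverse ratios of 0.900 for raised genes, as selection alone can give, but 1.08 for lowered genes. The PRMT5i effect on lowered genes was thus weaker with EZH2i under either choice of genes, and on raised genes under 1 choice only. No spread was estimated for these inverse ratios. Opposing action of the enzymes at these genes therefore remains a hypothesis.

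Other splits of the libraries into groups of the same sizes were run for each comparison. PRMT5i against DMSO gave 5847 genes and the highest other split 50 (1 of 35 splits as large, the real one included). Chance is thus an unlikely source of this count, though 1 of 35 is the smallest share that these splits can give. The same holds for the combination against DMSO (5990), against PRMT5i (688) and against EZH2i (4633), with 1 of 35 splits as large in each and 0 as the highest other in edgeR. For gene lists chance is not excluded: 8 of 35 splits gave as many as the 9 lists for PRMT5i (highest other 9), 8 of 35 as many as the 10 for the combination against DMSO (11), 2 of 35 as many as the 11 against PRMT5i (12), and 3 of 35 as many as the 12 against EZH2i (13). Of 100 splits 1 gave as many as the 280 genes lower with PRMT5i and higher with EZH2i added (highest other 67). Regrouping removes the PRMT5i effect itself, so these splits cannot decide on chance for that number. For the 108 opposed between the single inhibitors 1 of 100 splits gave as many and the highest other 0 in edgeR. As no other split called an opposed gene, this shows only that regrouping does not make such calls. The 108 lie below the 124 of independent lists, so no surplus of shared genes is shown. For the correlation of 0.268 chance is not excluded, since 84 of 100 splits gave one as high (highest other 0.858).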
